A study of Homo sapiens with 3 samples.

How the data were processed

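RNA from MDA-MB-231 cells was measured by RNA sequencing in 3 libraries of 1 group, control siRNA, which the labels call biological replicates. Per the labels, cells were transfected at 50 nM on 2 occasions 24 h apart and harvested 48 h after the second, and TruSeq RNA libraries were read as pairs of 100 bp. The deposited files hold raw counts per RefSeq transcript record, as whole numbers with no normalization; the submitters' processing notes name FastQC, TopHat2 and Cufflinks and the build hg19. Versions, the counting tool, the strand setting and the handling of reads with several hits are not stated. Other samples of the study, and mitochondrially encoded genes, BUB1B and INS, are not analysed here.

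Each library holds 42269 records with 39005 distinct record identifiers, and record counts summed to 136743528, 168901029 and 108482481 in replicates 1, 2 and 3. Records of the same gene held nearly the same counts in replicate 1 (5364 genes with several records and 100 or more counts, median ratio of lowest to highest record 0.938). From this it was inferred that a read was counted for each record it overlaps, and exon sharing itself was not examined. A gene's count was therefore the largest over its records, after summing a record's copies on alternative haplotypes (1006 identifiers with copies). Of 6937 records without a gene name, 6318 were matched by accession, and the 619 others held 0.952%, 0.959% and 0.944% of the record totals. For 28 genes whose symbol had become a date number, the symbol was restored from the Entrez identifier. This gave 22825 genes, 18740 with a count, and gene totals of 68670363, 84888346 and 54517311. TPM used transcript lengths from GENCODE 29, found for 97.8% of genes with a count.

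Library sizes were scaled with edgeR 4.0.16 (TMM) in R 4.3.3, and genes were filtered with filterByExpr without groups. Variation beyond counting noise was the deviance of an intercept-only edgeR fit with dispersion 0 against a chi-square, adjusted by Benjamini-Hochberg and called at 0.05. Dispersion came from edgeR estimateDisp, and DESeq2 1.42.0 served as an alternative. List tests ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots in matplotlib 3.10.9.

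Before the data were examined, 35 gene lists with 413 members, 7 contrasts between them, the tests and a first set of alternatives were fixed; 34 lists could be measured. List levels used log2(TPM + 1), with percentiles among 10000 random lists of the same size, drawn with replacement. Contrasts permuted genes between lists, two-sided, exactly with fewer than 10 genes in a list and otherwise with 100000 resamples. Genes in a list are not independent replicates, so these p describe the genes of these libraries. For spread and for shift in a single library, members' log2(CPM + 0.5) were compared with 10000 random lists, drawn by permuting genes within 20 bins of mean level (random-list permutation, two-sided), for 30 lists with 5 or more members. These lists were first drawn with replacement and then, after the results were seen, redrawn without it; the same 1 spread and 4 shifts were called. Adjustment was over 7 contrasts, 30 spreads and 90 shifts.

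The genes named are, by a rule also fixed then, the 2 highest members and the lowest member of each list, all catalytic subunits of the proteasome, ESR1, PGR, ERBB2, VIM, CDH1 and EPCAM, and the 10 genes of highest level. The rule adds the 20 varying genes of widest range with a mean of 10 CPM or more, and up to 4 members of widest range in lists past a threshold. It names 146 genes, some of which are not reported here. Other genes (the genes low in replicate 3, KRT17, and CSF2 and CXCL1 among the cytokines) were chosen after their values were seen.

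The tests were tried on simulated data. Counts for the tests of single genes were drawn without paired mates, and those for the list tests as pairs. The false calls and recovered coefficients for single genes therefore do not carry over to counts that hold both mates. With counting noise alone, 74% of genes changed 1.25-fold, 90% changed 1.5-fold and 96% changed 2-fold in 1 library were called, with 6 false calls among 14371 genes. With a coefficient of variation of 0.05 added and allowed for, the shares were 26%, 74% and 98%, with 4 false calls among 14360 genes. Simulated coefficients of variation of 0 and 0.05 were recovered as 0.00988 and 0.0495 without changed genes, and came out as 0.0597 and 0.0794 in the sets with 50 genes changed at each of 4 fold sizes. When the fitted trends with GC content and length were added to counts without other variation, 3419 genes were called without offsets and 0 with them. Among 40 null lists none was called, and a shift of 0.3 was recovered as 0.28.

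Alternatives covered normalization, filters, pseudocounts, length, the summary of a list and each library left out. Those added after seeing the data were counting each pair once, summing over records, the largest copy alone, and removing trends with GC content and length (per library, splines for single genes and a quadratic for lists), alone or with each pair counted once. Counting each pair once was an approximation that scaled down each gene's deviance, and reads were not recounted.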

Results

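RNA was sequenced from 3 biological replicate cultures of MDA-MB-231, a human triple-negative breast cancer cell line, all transfected with a control siRNA. The labels place these libraries in 1 group (n = 3), and the study's other siRNA arm is not analysed here. The libraries therefore describe the baseline state of the transfected line and the spread between its replicate cultures, and no effect of a treatment can be tested. The title of the study concerns the proteasome, so the genes of that complex come first. The counts summed over genes came to 68670363, 84888346 and 54517311 in replicates 1, 2 and 3, and 12682 genes reached 1 CPM (counts scaled by library size) in each library. Levels of single genes are in TPM (counts scaled by transcript length and library size), and levels of gene lists are the median log2 level of the members minus that of all detected genes, both as mean ± SD over the 3 libraries (n = 3). A gene with 0 counts could still have lain at up to 0.0878, 0.0708 or 0.109 CPM in replicates 1, 2 and 3, the level of 3 read pairs with both mates counted (6 counts), and these limits cover counting error only. How reads from near-identical gene copies were handled is not stated, so levels of genes with such copies are uncertain.

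All 33 structural genes of the proteasome, the complex that degrades ubiquitin-tagged proteins, lay above the median detected gene. The 14 genes of the 20S core, the barrel that holds the proteolytic sites, had a list level of 3.91 ± 0.09, with PSMA7 at 686 ± 10.1 TPM, PSMA6 at 553 ± 19.1 TPM and PSMA5 lowest at 123 ± 2.60 TPM. In the 19S cap, which unfolds and feeds in substrates, the 6 ATPase genes were at 3.001 ± 0.02 and the 13 non-ATPase genes at 3.09 ± 0.05. Among the ATPases PSMC3 stood at 423 ± 20.2, PSMC5 at 332 ± 10.1 and PSMC1 at 125 ± 3.14 TPM. Among the non-ATPases PSMD2 stood at 651 ± 11.7, the ubiquitin receptor ADRM1 at 376 ± 21.8 and PSMD12 at 56.9 ± 3.55 TPM.

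The 20S core genes exceeded the 19S genes by 0.84 in median log2 TPM (permutation of genes between the lists, two-sided, p = 0.0149, adjusted p = 0.026 over 7 list contrasts; difference per library 0.86 ± 0.07, positive in 3 of 3 libraries). That difference depended on the correction for transcript length. In CPM it was 0.14 with an adjusted p of 0.535, and over the 8 alternatives tried the adjusted p ran from 0.00381 to 0.535. The 33 proteasome genes together exceeded 13 genes of the lysosome and autophagy, the cell's other degradation route, by 1.56 (permutation p = 0.00066, adjusted p = 0.00154; 1.56 ± 0.12 per library, positive in 3 of 3).

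The 3 constitutive catalytic subunits were PSMB7 (Entrez gene 5695) at 516 ± 3.67, PSMB6 (5694) at 350.1 ± 24.2 and PSMB5 (5693) at 214 ± 14.7 TPM. Their counterparts in the immunoproteasome, the interferon-inducible form that favours peptides for antigen presentation, were all transcribed, with PSMB8 (5696) at 175 ± 3.01, PSMB10 (5699) at 144 ± 5.96 and PSMB9 (5698) at 121 ± 11.8 TPM. Each constitutive subunit lay above each inducible one, and the list medians differed by 1.28 log2 units (exact permutation p = 0.2, adjusted p = 0.28; 1.28 ± 0.06 per library, positive in 3 of 3). With 3 against 3 genes, this comparison of medians cannot give an exact p under 0.2. The test was thus at its limit and could not have passed, so it does not decide the question. PSMB8 and PSMB9 lie in the MHC region and have 8 copies each in the counted annotation, over which their counts were summed. With the largest copy alone PSMB8 was at 23.8 ± 1.26 and PSMB9 at 19.3 ± 2.78 TPM, and the difference between the lists was 3.86. In CPM that difference was 0.76, so its size is uncertain. The proteasome activators and assembly factors were lower as a list, at 1.56 ± 0.02, although the subunits of the interferon-inducible activator were high, with PSME1 at 649 ± 7.34 and PSME2 at 357 ± 8.80 TPM. The lowest of the 14 was the assembly chaperone PAAF1, at 8.06 ± 0.408 TPM.

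**Figure D1:**
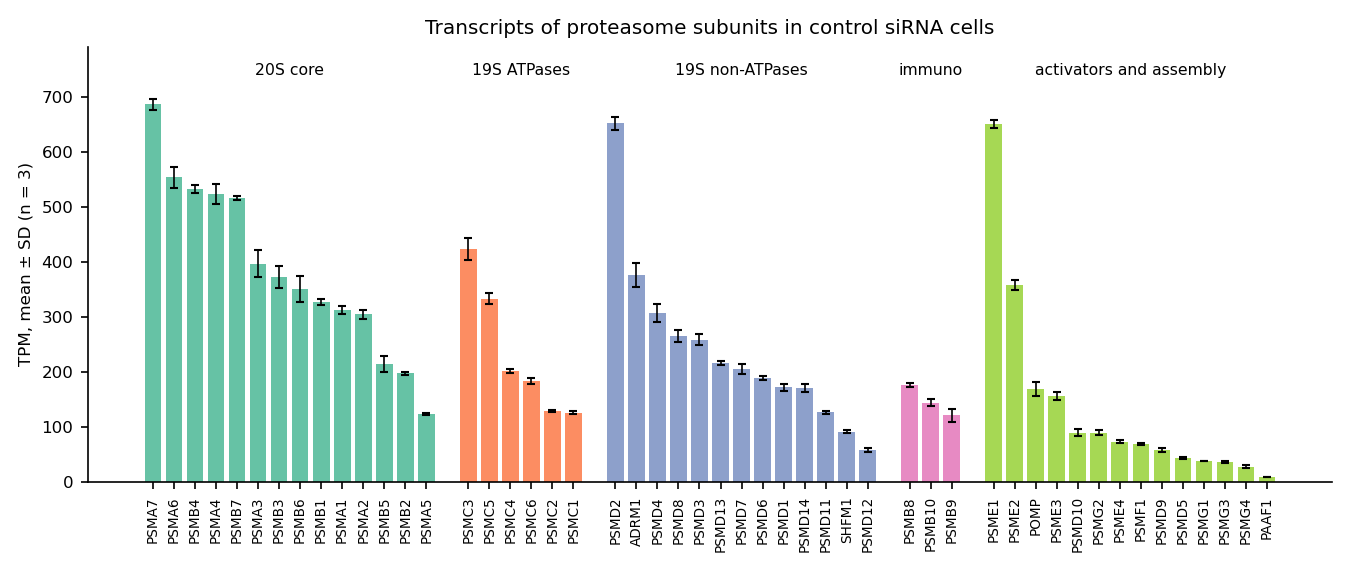
Level of each proteasome gene in TPM, grouped by part of the complex; bars are means and error bars SD over 3 replicate libraries. The constitutive catalytic subunits lie between 214 and 516 TPM and the immunoproteasome subunits between 121 and 175 TPM. PSMB8 and PSMB9 are summed over 8 copies each, and with the largest copy alone are at 23.8 and 19.3 TPM.

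The protein quality control genes around the proteasome were also strongly transcribed. Ubiquitin and proteasome regulation had a list level of 3.37 ± 0.06, led by the ubiquitin precursor genes RPS27A at 1947.5 ± 55.0 and UBB at 972 ± 40.04 TPM. DDI2, the protease that activates the proteasome gene regulator NFE2L1, was lowest at 3.01 ± 0.191 TPM. Cytosolic chaperones were at 2.83 ± 0.04, with HSP90AB1 at 2089 ± 39.4, HSPA8 at 1539 ± 18.4 and HSPH1 lowest at 95.3 ± 6.14 TPM. That lowest place rests on summing HSPA1A and HSPA1B over 5 copies each. With the largest copy alone these were at 21.9 ± 1.29 and 35.4 ± 1.46 TPM. The ER stress list was at 1.34 ± 0.12, where the lumenal chaperones CALR and HSP90B1 reached 2365 ± 29.04 and 1003 ± 64.5 TPM and CHAC1, a stress-induced glutathione-degrading enzyme, only 7.42 ± 0.769 TPM. Targets of NRF2, the oxidative stress regulator, were at 2.67 ± 0.01, from the ferritin genes FTL (1521 ± 54.5 TPM) and FTH1 (1163 ± 26.0 TPM) down to the haem oxygenase HMOX1 (6.95 ± 0.289 TPM). The lysosome and autophagy list was at 1.90 ± 0.06, with the cathepsins CTSD at 2348 ± 84.6 and CTSB at 365 ± 11.3 TPM and the lysosomal regulator TFEB at 3.02 ± 0.209 TPM.

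Proliferation genes were highly transcribed. Mitosis genes were at 2.96 ± 0.05, with TOP2A, which untangles chromosomes, at 492 ± 21.4, the anaphase activator CDC20 at 416 ± 21.3 and BIRC5 lowest at 89.0 ± 0.653 TPM. DNA replication genes were at 2.44 ± 0.03, with the sliding clamp PCNA at 393 ± 11.2, TYMS at 378 ± 8.12 and POLA1 at 23.9 ± 1.12 TPM. Cell cycle arrest and DNA damage response genes were at -0.44 ± 0.05, inside the range of random lists (percentile 26.6), with the death receptor TNFRSF10B at 115 ± 2.47, BAX at 106 ± 2.61 and the antiproliferative BTG2 at 0.343 ± 0.126 TPM. The 14 mitosis genes exceeded the 16 arrest genes by 3.40 (permutation p = 8e-05, adjusted p = 0.00056; 3.40 ± 0.10 per library, positive in 3 of 3). Replication-dependent histone genes, whose transcripts largely lack poly(A) tails, were at -3.08 ± 0.16. Their highest members were HIST1H2BK at 142 ± 4.35 and HIST1H1C at 35.5 ± 1.88 TPM, and HIST1H1D had no counts.

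Glycolysis genes had a list level of 5.97 ± 0.07, with GAPDH at 5453 ± 89.3 and PKM2, the name the files give the pyruvate kinase gene PKM, at 4595 ± 46.0 TPM; hexokinase HK2 was lowest at 81.3 ± 1.55 TPM. The nuclear genes of the respiratory chain were at 2.82 ± 0.05, with the ATP synthase genes ATP5B at 848 ± 13.9 and ATP5A1 at 639 ± 16.5 and the complex I gene NDUFS1 at 31.7 ± 1.14 TPM. The 12 glycolysis genes exceeded the 14 respiratory genes by 3.15 (permutation p = 0.00058, adjusted p = 0.00154; 3.15 ± 0.01 per library, positive in 3 of 3). Ribosomal protein genes had the highest level of the 34 lists measured, 6.17 ± 0.06, with RPS18 at 6796 ± 100.3 (summed over 6 copies in the MHC region; 1391.5 ± 8.01 with the largest copy alone), RPLP0 at 4343 ± 174 and RPL13 at 415 ± 22.5 TPM. Cholesterol synthesis genes were at 1.01 ± 0.04 (percentile 95.3), with FDPS at 303 ± 3.35 and SQLE lowest at 15.4 ± 0.991 TPM.

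Markers of breast cell identity were mixed, with some abundant mesenchymal and basal genes beside abundant simple epithelial keratins. The intermediate filament gene VIM was at 4413 ± 157 and S100A4 at 3123.5 ± 8.31 TPM, while TWIST1, a transcription factor of the mesenchymal programme, had no counts. Adhesion genes of epithelial cells were low to moderate, with CDH1, the E-cadherin gene, at 0.586 ± 0.222 and EPCAM at 17.1 ± 1.20 TPM, but the simple epithelial keratins KRT8 and KRT19 were at 723 ± 39.6 and 639 ± 49.8 TPM. The epithelial regulator OVOL2 was the lowest of its list, at 0.110 ± 0.0992 TPM. Hormone receptor genes were low, with the oestrogen receptor ESR1 at 0.0116 ± 0.00461 TPM on 3, 3 and 1 counts and the progesterone receptor PGR at 0.0582 ± 0.00142 TPM on 23, 30 and 19 counts, and ERBB2, the HER2 gene, was at 27.9 ± 1.63 TPM. Of the luminal genes MLPH and AGR2 were the highest, at 102 ± 3.44 and 85.5 ± 0.859 TPM, and TBX3 was lowest, with counts in 1 library alone.

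Basal breast genes were at 1.70 ± 0.05 (0.85 as a mean over members), and 8 of 12 reached 1 CPM in each library. They were led by ANXA1 at 1133 ± 46.7 and MSN at 729 ± 8.58 TPM, whereas the basal keratin KRT14 was at 0.1503 ± 0.0468 TPM. Luminal genes were at -1.24 ± 0.12, mesenchymal genes at 0.82 ± 0.04 and epithelial genes at -1.03 ± 0.06. Neither contrast passed its test. The basal list exceeded the luminal one by 2.93 (12 genes each; permutation p = 0.252, adjusted p = 0.294; 2.93 ± 0.16 per library), and by 4.68 in CPM. The mesenchymal list exceeded the epithelial one by 1.85 (12 genes each; permutation p = 0.562, adjusted p = 0.562; 1.85 ± 0.02 per library), and by 3.02 with counts summed over the records of each gene. Both differences were positive in 3 of 3 libraries. Invasion and proteolysis genes were at 2.13 ± 0.09, with the integrin gene ITGB1 at 737 ± 40.5 and the urokinase gene PLAU at 526 ± 16.4 TPM but MMP9 at 0.0395 ± 0.0136 TPM. Targets of the growth regulator YAP were at 2.19 ± 0.04, with the receptor kinase AXL at 569 ± 40.5, CYR61 at 301 ± 12.3 and LATS2 at 12.7 ± 0.488 TPM.

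Innate immune and stress signalling genes had list levels between -1.23 and 0.39, and some of these changed sign with the scale. Interferon response genes were at 0.10 ± 0.17 (-0.44 in CPM and -0.26 as a mean over members), with ISG15 at 111 ± 7.27 and IFI44L at 0.599 ± 0.199 TPM. Inflammatory cytokines were at -1.23 ± 0.22, with NFKBIA, a feedback inhibitor of NF-kB, at 143 ± 8.68 and the chemokine IL8 at 52.5 ± 8.46 TPM. CCL2, another chemokine, had counts in replicate 2 alone, and there only 3. Immediate early genes were at 0.39 ± 0.08 (-0.08 in CPM), where IER3, summed over 6 copies, and FOSL1 reached 598 ± 20.04 and 308 ± 10.9 TPM (IER3 145 ± 9.08 with the largest copy alone) and FOSB was at 0.711 ± 0.0297 TPM. The small RNA silencing machinery, which makes and loads microRNAs, was at -0.55 ± 0.04 in TPM but at 0.93 in CPM, with the exporter XPO5 at 103 ± 3.78, DROSHA at 46.5 ± 1.71 and the Argonaute gene EIF2C3 at 2.05 ± 0.211 TPM. Reference genes used in quantitative PCR were at 2.58 ± 0.02, spanning ACTB at 5476 ± 195 to TBP at 20.4 ± 1.88 TPM.

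Markers of other cell types were low, as lists. Leukocyte markers were at -3.39 ± 0.12, endothelial markers at -4.52 ± 0.02, fibroblast markers at -4.43 ± 0.04 and markers of other tissues at -4.48 ± 0.10, with 5 of 10, 2 of 8, 3 of 10 and 1 of 9 members detected (1 CPM or more in each library). Single members were nonetheless abundant, among them the lysosomal protein gene CD68 at 178 ± 1.90 and the MHC class II gene HLA-DRA at 154 ± 2.33 TPM, the latter summed over 7 copies of its region (31.4 ± 1.47 with the largest copy alone). In the endothelial list KDR was at 1.11 ± 0.0737 and PECAM1 at 1.03 ± 0.172 TPM. In the fibroblast list COL1A1 was at 11.4 ± 1.40 and ACTA2 at 4.78 ± 0.416 TPM. Of the markers of other tissues GFAP was at 2.32 ± 0.123 and APOA1 at 1.43 ± 0.371 TPM. The endothelial factor ERG, the matrix gene DCN and the lung gene SFTPC had no counts.

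**Figure D2:**
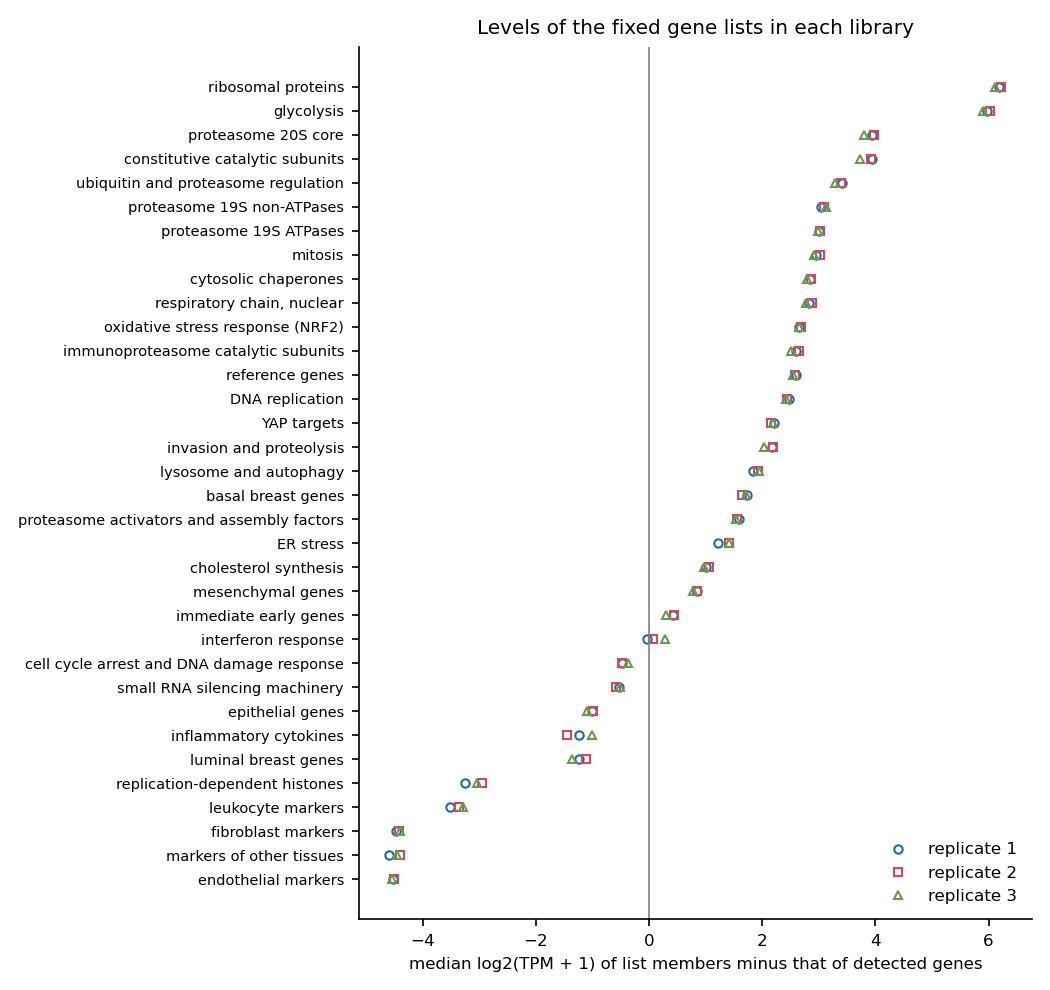
Level of each of the 34 measured gene lists, as the median log2(TPM + 1) of its members minus that of all detected genes, with 1 point per replicate library. Ribosomal proteins (6.17) and glycolysis (5.97) lie highest and endothelial markers (-4.52) lowest.

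Of the 34 lists, 24 lay in either tail of the random lists, at or below percentile 2.5 or as far out at the top, and the immunoproteasome subunits were at percentile 97.48. The random lists were drawn from genes that reached 1 CPM in some library, so the place of the 5 lists in the lower tail, the histones and the markers of other cell types, follows largely from how few of their members did. The 10 genes of highest level were S100A6 at 12190.0 ± 459, RPS18 (place 101 with its largest copy alone), EEF1A1 at 5679 ± 141, ACTB, GAPDH, TMSB4X at 5245 ± 92.6, RPL13AP5 at 5101 ± 74.5, TMSB10 at 4718 ± 56.1, PKM2 and VIM. S100A6 encodes a calcium-binding protein and TMSB4X and TMSB10 encode thymosins, which bind actin monomers. RPL13AP5 is a pseudogene of a ribosomal protein gene, so its reads cannot be assigned to it with certainty. The 10 genes with the most counts took 4.74%, 4.92% and 4.60% of the counts in replicates 1, 2 and 3.

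The replicate cultures were close to each other, with a common biological coefficient of variation of 0.0544. In counting noise simulated without paired mates, 50 genes changed in 1 library at each of 4 fold sizes were enough to give 0.0597. In the data the coefficient was 0.136 for genes at 1 CPM and 0.0438 at 256 CPM. Even so, 7650 of 14422 tested genes (53.0%) varied beyond counting noise at an adjusted p under 0.05 (edgeR deviance against a chi-square). Genes with exactly 2 counts (712, 637 and 580 in replicates 1, 2 and 3) outnumbered those with 1 (485, 401 and 379), the pattern left when both mates of a read pair are counted. To stand for each pair counted once, each gene's deviance was divided by 2, as if every count came from a full pair. Reads were not recounted, and some genes had odd counts, so this is an approximation. With each pair counted once in this way, 4103 genes (28.4%) varied. Without replicate 3, and with the deviance undivided, the number was 3567 of 14744. Allowing for a coefficient of variation of 0.05 between cultures left 158 genes, and of 0.1 left 18. The coefficients of the data given above came from the counts as deposited, where counting both mates would add counting error, most at low counts. Their values with each pair counted once were not computed.

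Among varying genes with a mean of 10 CPM or more, the 20 with the largest range were headed by ribosomal RNA. RNA5-8SN5, a 5.8S ribosomal RNA, stood at 14.2, 34.4 and 14.4 CPM in replicates 1, 2 and 3, and the ribosomal RNA precursor RNA45SN5 at 2742, 4560 and 2224 CPM. The nuclear long noncoding RNA MALAT1 was lowest in replicate 2, at 426, 271 and 454 CPM, and the zinc finger gene ZNF460 highest there, at 6.41, 14.9 and 10.0 CPM. The other 16 were within 1.57-fold. The largest of these were C5orf34 at 8.18, 10.9 and 12.9 CPM, C4orf48 at 15.7, 11.7 and 10.8 CPM, the centromere gene CENPH at 14.3, 17.4 and 20.7 CPM and the nucleosome-binding gene HMGN5 at 13.6, 12.8 and 18.2 CPM. The polarity gene LLGL2 was at 21.03, 17.8 and 14.8 CPM, and the epidermal gene FLG at 57.2, 41.2 and 49.5 CPM. The remaining 10 were SGK196, USP45, ATPAF2, MAPK12, KIAA1586, SAMD10, ABCA5, SELO, FRG1BP and RGS19.

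Part of the difference between libraries followed base composition. Across 13767 genes, which are not independent replicates, each library's deviation from the gene mean had a Spearman correlation with GC content of 0.43, 0.26 and -0.55 in replicates 1, 2 and 3. Genes in the lowest of 10 GC bins (median 37.4%) had a median deviation of -0.05, -0.02 and 0.07, and those in the highest (64.5%) of 0.06, 0.03 and -0.09. With GC content and length fitted as offsets, 5561 genes (38.6%) varied beyond counting noise.

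**Figure D3:**
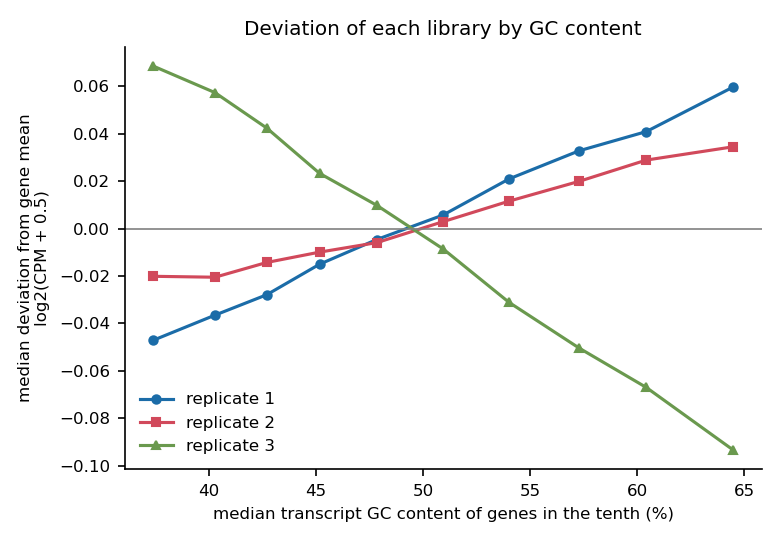
Median log2 deviation of genes from their mean over the 3 libraries, in 10 bins of GC content, with 1 line per replicate library. Replicate 3 runs from 0.07 in the lowest bin to -0.09 in the highest, and replicates 1 and 2 run the other way.

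Few of the gene lists differed as groups between the replicate cultures. Of 30 lists with at least 5 tested members, 1 varied more than random lists of the same abundance, the inflammatory cytokines (12 members, median SD 0.21 against 0.09; random-list permutation, p = 0.0002, adjusted p = 0.006; 0.0002 is the smallest p these lists can give). Its members of largest range were the chemokines CCL20 at 0.527, 0.814 and 0.237 CPM and CXCL3 at 1.71, 1.003 and 0.948 CPM, and the cytokines IL1A at 1.96, 2.03 and 1.31 CPM and IL6 at 4.73, 4.0005 and 5.59 CPM. With any 1 library left out the adjusted p was 0.32, 0.63 or 0.09, for replicates 1, 2 and 3.

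In 90 tests of a list in a single library, 4 passed, all in replicate 2, the library that also held the most RNA45SN5 (4560 CPM) and RNA5-8SN5 (34.4 CPM) and the least MALAT1 (271 CPM). Inflammatory cytokines were lower there by a median log2 deviation of -0.12 (3 of 12 members higher; random-list permutation, p = 0.0002, adjusted p = 0.018), with IL6 at -0.22, IL8 at -0.22, CSF2 at -0.21 and CXCL1 at -0.20, while CCL20 was at 0.40. Glycolysis genes were higher by 0.05 (12 of 12 members; permutation p = 0.001, adjusted p = 0.027), with the genes of widest range GPI at 579, 605 and 543 CPM and PFKP at 491, 493 and 443 CPM, followed by ALDOA and PGAM1. Nuclear respiratory chain genes were higher by 0.05 (14 of 14; permutation p = 0.0004, adjusted p = 0.018), with COX6C at 88.1, 97.3 and 100.7 CPM and NDUFV1 at 89.0, 90.6 and 79.8 CPM, followed by UQCRC1 and NDUFA4. Ribosomal protein genes were higher by 0.05 (15 of 15; permutation p = 0.0012, adjusted p = 0.027), with RPL8 at 1121, 1138 and 1006 CPM and RPL13 at 836, 837 and 746 CPM, followed by RPL18 and RPS3. With the trends with GC content and length removed, the cytokines were at -0.13 (adjusted p = 0.017) and the other lists at 0.03 each, with adjusted p of 0.11, 0.062 and 0.076. In replicate 3 the glycolysis, respiratory and ribosomal lists lay the other way, at -0.06, -0.04 and -0.06 (1 of 12, 5 of 14 and 3 of 15 members higher; permutation, adjusted p = 0.33, 0.33 and 0.14), and in replicate 1 at 0.01, -0.02 and 0.01. Without replicate 3 the glycolysis and ribosomal lists were no longer called, at 0.01 and 0.02 (adjusted p = 0.25 and 0.097), the respiratory list was at 0.02 (adjusted p = 0.023), and the cytokines were at -0.08 without replicate 1 or 3 (adjusted p = 0.034 and 0.006).

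Several genes that replicates 1 and 2 held at low level, some keratins among them, had no or few counts in replicate 3; those named here were chosen after their values were seen. KRT6A, a keratin of activated and stratified epithelium, had 471, 461 and 0 counts in replicates 1, 2 and 3, at least 56.4-fold lower in replicate 3 than the mean of 6.17 ± 1.03 CPM in the other libraries (n = 2; bound against 3 read pairs, 6 counts). KRT5, a keratin of basal epithelial cells, had 392, 459 and 0 counts, at least 51.0-fold lower than 5.58 ± 0.226 CPM. SERPINB5, the epithelial gene for maspin, had 44, 68 and 0 counts and the chemokine CXCL5 had 55, 50 and 0, at least 6.61-fold and 6.38-fold lower. The hair keratin KRT81 was 6.08-fold and the aminopeptidase ANPEP 14.5-fold lower there, on 32 and 7 counts, and the fibrillin FBN2 had 62, 59 and 3 counts. KRT6A, KRT6B and KRT6C are near-identical, so the split of reads among them is uncertain.

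In all, 32 genes with a mean of 0.1 CPM or more were, by their counts, at most 0.25 times the lower of the other libraries in replicate 3 (adjusted p under 0.05 with each pair counted once, deviance from a common level), 22 of them with 0 counts. The same number was 8 for replicate 1 and 4 for replicate 2. With counts under 6 raised to 6, the level that 0 counts allow, it was 2, 2 and 8 for replicates 1, 2 and 3, and the 8 were KRT6A, KRT5, KRT81, ANPEP, FBN2, SERPINB5, S100A14 and CXCL5. The adjusted p is for any deviation from a common level, so genes high in 1 other library also entered the 32. Examples are CHRNB2 with 8, 44 and 0 counts and KCNH3 with 33, 6 and 0. Genes at 4 times or more the higher of the other libraries numbered 5, 8 and 2 in replicates 1, 2 and 3. Whether the 32 are richer in epithelial genes than chance was not tested. KRT5 and KRT6A were not among the 14422 genes above, because that filter asked for counts in each library. The fixed epithelial and luminal lists had median deviations of -0.11 (2 of 11 members higher) and -0.10 (1 of 10 higher) in replicate 3 (random-list permutation, p = 0.0028 and 0.0058, adjusted p = 0.05 and 0.075). Neither was called, and with the trends with GC content and length removed they were at -0.05 each (permutation, adjusted p = 0.14 each). The fixed basal list, tested without KRT5, showed no such shift in replicate 3, at -0.003 (4 of 9 members higher; random-list permutation, p = 0.94, adjusted p = 0.99). CDH1 had 120, 97 and 45 counts and the basal keratin KRT17 124, 116 and 29.

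**Figure D4:**
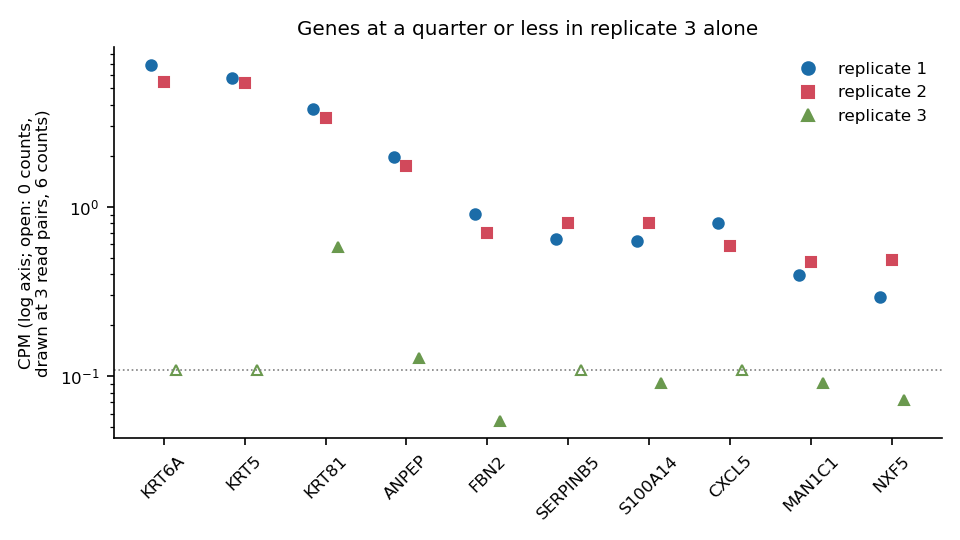
Level in CPM (log axis) of the 10 most abundant of the 32 genes that by their counts are at most 0.25 times the other libraries in replicate 3, with 1 point per replicate library; open points have 0 counts and are drawn at the level of 3 read pairs (6 counts). KRT6A and KRT5 average 6.17 and 5.58 CPM in replicates 1 and 2 and have no counts in replicate 3, where that level is 0.109 CPM.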

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

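Alternatives that count each pair once, remove trends with GC content and length, sum over records or take the largest copy were chosen after the results were seen. The number of genes detected and the common coefficient of variation stayed within 1.5 times their values under 7 of 7 alternatives each, none of which counted each pair once. No result that passed a test or lay in a tail of the random lists changed sign. The number of varying genes stayed within 1.5 times its value under 7 of 12. It was 158 and 18 with a coefficient of variation of 0.05 and 0.1 between cultures, 4103 with each pair counted once, 1908 with trends removed as well, and 3567 to 5647 with 1 library left out. The drops with an allowed coefficient of variation follow from the wider noise model, and for the others the cause was not tested.

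Of the 7 list contrasts, 6 kept their direction and side of the threshold under all 8 alternatives. For the constitutive and inducible catalytic subunits that side was fixed in advance, since lists so short cannot pass. The difference between 20S and 19S genes was 0.14 in CPM (adjusted p = 0.535), where longer transcripts collect more reads. The 24 lists outside the range of random lists were 24 to 26 under the alternatives, but 3 lists inside it changed sign in CPM: silencing machinery to 0.93, interferon response to -0.44 (-0.26 as a mean) and immediate early genes to -0.08. The size of a level depended more on the setting, and in 72 cases it moved by its SD over libraries or more. The constitutive subunits went from 3.86 to 2.06 in CPM, and the endothelial markers from -4.52 to -7.29 with a pseudocount of 0.1. The number of list shifts called was 7 with genes of 5 CPM or more and 1 with trends removed, and the cause was not tested. It was 2 to 14 with 1 library left out. There a gene's deviation in 1 of the 2 libraries mirrors that in the other. Each called list thus counts in both, and these numbers cannot be set against the main one. The single call for list spread was lost, giving 0, whichever library was left out, which leaves 2 values per gene. Depth limits the genes near 0: a count of 0 allows levels of up to 0.0708 to 0.109 CPM.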

Other observations

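Tests chosen only after the result was seen were those of counting noise for the keratins, of mates counted separately, and of the trends for the cytokines and for the epithelial markers. Members of 5 CPM or more were an alternative fixed before the data were examined, and their use against few counts came after the cytokine result. Removal of the trends, as offsets or from the levels, was added after the data were seen. No biological explanation was tested, since the labels give 1 group; RNA or reads of other cells count here as a technical source.

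KRT5, KRT6A, KRT6B, KRT6C and other genes had 0 counts in replicate 3 alone. Counting noise is argued against as the whole source. In replicate 3, 67 genes were at most 0.25 times the lower of the other libraries, by fold alone, where 100 simulated sets gave at most 35 (22 against 29 in replicate 1 and 9 against 21 in replicate 2). For the 32 genes called low in replicate 3, the trends with GC content and length gave a median deviation of -0.0313 against an observed -0.37. Those 32 were picked as low there, so the observed median is large by selection. The comparison shows only that the fitted trends alone fell short of these deviations, and it cannot exclude a part for them. RNA or reads of other epithelial cells in replicates 1 and 2 remain a candidate source: of 50 epithelial markers listed before the test, the 25 with a mean under 2 CPM had a median deviation of -0.0861 in replicate 3 (random-list permutation, p = 0.0008; 22 of 25 lower; -0.0848 with the trends removed, p = 0.0004, and p = 0.001 with lists matched on GC content too) against 0.04 in replicate 1 (p = 0.019) and 0.03 in replicate 2 (p = 0.2). Of the better-counted of these 25, ST14 had 123, 130 and 60 counts. LCN2 did not fall, at 1.04, 1.05 and 1.08 CPM, and FAT2 fell little, at 0.585, 0.566 and 0.510 CPM. Summed over the 25, the level was 5.33, 5.42 and 3.68 CPM in replicates 1, 2 and 3, a far smaller drop than those of KRT5 and KRT6A. Many of the 25 held few counts, such as KLK5 with 4, 3 and 0 and SPRR1A with 0, 1 and 0. Members with so few counts lie under the level that 0 counts allow, so their single directions are uncertain. The line itself transcribes other markers of the 50, such as LAMB3 at 722, ITGB4 at 339 and KRT7 at 275.5 CPM. KRT14, which skin keratinocytes make with KRT5, had 5, 12 and 6 counts, which argues against those cells. A small subpopulation of the line itself, lost from replicate 3, stays open and was not tested.

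Of the tested genes, 53.0% varied beyond counting noise. Neither mates counted separately (4103 genes with each pair counted once, 28.4%), nor trends with GC content and length (5561 genes with both as offsets, 38.6%), nor both together (1908 genes, 13.2%) brought the share to the 5% set as the bound. Each change lowered the number, so these may account for part of it. What the rest reflects, in culture, transfection or library preparation, stays open.

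Inflammatory cytokines were lower in replicate 2. The trends are argued against as the whole source, since with both removed the median was -0.13 (adjusted p = 0.017; 0.006 to 0.034 over the alternatives tried). Members with few counts are argued against, since those of 5 CPM or more gave -0.12 (adjusted p = 0.016). Replicate 2 also stood apart in ribosomal RNA precursor (RNA45SN5 at 2742, 4560 and 2224 CPM in replicates 1, 2 and 3) and MALAT1 (426, 271 and 454 CPM), so a difference in RNA composition or preparation stays open beside one in the cultures themselves, and neither was tested.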
